A study of Panicum virgatum with 24 samples.

How the data were processed

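The series holds 24 RNA-seq libraries of switchgrass (Panicum virgatum, cultivar Alamo), an allotetraploid grass with a K and an N subgenome. They form 8 groups of 3 libraries, from roots and shoots at an optimal supply and at 200, 60 and 20 µM phosphorus (P), each after 4 weeks of growth in a sand and perlite mix. Per the labels' protocols, total RNA was extracted with a CTAB and lithium chloride method and made into libraries with an Illumina TruSeq RNA kit. HISAT2 2.0.5, StringTie 1.2.4 and Cuffdiff are named, without a role, in the submitters' processing notes. The genome build is not named in the sources used here, though some locus names in the deposited tables end in v4.1.

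The files analysed here are 6 tables of the authors' own comparisons, each with 99409 loci. Of these, 3 set control roots against roots at 200, 60 and 20 µM P. The other 3 set control roots against groups named N2R, N06R and N02R, which the labels do not describe. Shoot comparisons were not analysed here. Per the file headers, the columns are those that DESeq2 writes, with 1 value per locus and comparison. The deposited baseMean column, a signal, holds the mean normalised count over all libraries of the authors' fit. It was identical in the 6 tables, so it is a level across the whole fit and not a root level. The deposited log2 fold changes carry the authors' standard errors (SE), and the deposited score (the Wald statistic) equals their quotient within 1.01e-13. The deposited p-values come with adjusted p-values, which the authors' table leaves empty for loci filtered before adjustment. Loci with an adjusted p are called tested below. No p-value was given for 754 loci, the same in all tables.

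The tables hold no values per library, so the depth of each library is unknown and no spread between replicates could be computed. Errors are the authors' SE. The labels do not say whether the 3 libraries of a group came from separate plants, so these p-values measure only the spread between libraries, which may be technical. Properties of the authors' fit were read from the values. The lowest baseMean values form 41 separate steps within a 2-fold range, more than the 24 described libraries could give at 1 step per library, so the fit appears to have held further libraries. No SE in any table exceeds 1.42, and the median SE at 20 µM P of loci under a baseMean of 0.05 is 0.91. A fit with a prior on the fold changes gives such a ceiling, and such a prior would understate the changes of weakly expressed loci.

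The deposited sign is control over P-limited, by the order of the groups in the table names and by the phosphate starvation genes. At 20 µM P, the deposited values of all called loci were negative in the lists of SPX and PHR regulators (8 of 8), phosphate transport (15 of 15) and membrane lipid remodelling (17 of 17). All values below were turned to P-limited over control. Because these 3 lists helped to set the sign, they are not independent evidence of direction.

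The planned tests assumed Cuffdiff gene tables. As fixed for files without replicate values, the authors' test was reported, with an adjusted p under 0.05 as a call. Genes were named by a rule written before the data were examined, as were 25 gene lists. At 20 µM P the rule takes the 8 largest rises, the 8 largest falls and up to 3 called members of each list. At 60 and 200 µM P it takes the 5 largest rises and falls and up to 2 called members of each of the 5 phosphate lists. Genes needed an annotation and a level of 1 or more, applied to baseMean. A further condition, values above 0 in both groups, could not be applied because group values are not given. The rule named 97 loci in all, 80 of them for 20 µM P, and those described were picked from these.

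List membership followed the best Arabidopsis hit in the deposited annotation, or a keyword where a list had no loci. For each list, calls were counted, calls were also adjusted over the list alone (Benjamini-Hochberg), and the median log2 fold change was placed among 10000 random lists of the same size matched in 20 bins of baseMean. The lists were also tested on the signed Wald statistic with cameraPR of limma 3.58.1 in R 4.3.3, with a preset correlation of 0.01 and adjustment over 25 lists. An estimated correlation needs values per library, so no call of this test could be examined with one. Chance values for comparisons sharing the control libraries came from 100 simulated sets of unchanged groups built from the authors' SE. Their noise was drawn separately for each locus, so shifts common to many loci are not in them. The part due to the control was assumed: the smallest squared SE of a locus over all comparisons was split equally between control and group. For the graded order, a reference added after the data had been seen gave every locus its mean change over the 3 supplies at each of them, with the same noise, calls and selection. Differences between P levels were tested with the sum of both squared SE, which is conservative because the control is shared. Enrichment of Gene Ontology terms with 10 to 500 tested loci (one-sided hypergeometric test) and a list of late embryogenesis abundant (LEA) and dehydrin genes were added after the data had been seen. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

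The calling step was tested on simulated data for 20 µM P over 70432 loci with 50 loci changed at each size. It recovered 24% of 2-fold, 62% of 4-fold, 84% of 8-fold and 96% of 16-fold changes, with 6 false calls and 0 calls in the wrong direction. Far fewer loci were changed than the 11728 called in the data, which alters the adjustment, so recovery in the data may differ. The noise followed the same SE that the test used, so the false calls do not check those SE. Of 100 simulated lists without a shift, 5 had a median outside the central 95% of random lists, as did 20 of 20 shifted lists. Alternatives were stricter thresholds, filters on baseMean, other centring of the fold changes and list membership by annotation text.

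Loci are named by the reference gene that the tables give, with the name of the best Arabidopsis or rice hit. Such a name marks sequence similarity, and it is not a tested function. The RefSeq gene table for assembly P.virgatum_v5 held 0 of the 68573 reference genes, so no coordinates are given. Reads of near-identical copies in the K and N subgenomes may have been divided between them, so the values of single copies are uncertain.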

Results

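RNA from switchgrass roots was sequenced after 4 weeks of growth at an optimal nutrient supply or at 200, 60 or 20 µM P, named mild, moderate and severe stress in the labels, with 3 libraries per group. The comparisons ask which root transcripts differ from the control at each supply, and whether the differences grow as P falls. The authors' deposited tables give 1 log2 fold change, SE and adjusted p per locus and comparison, so values below carry the authors' SE, and the depth per library is unknown. All values are P-limited over control.

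At 20 µM P, the roots had higher transcript levels of genes for phosphate uptake, phosphate release and phospholipid breakdown, and of genes for strigolactone synthesis. Genes for AWPM-19-like membrane proteins, a dehydrin and an LEA protein were among the largest falls. By the authors' deposited table, a PHT1;5-like phosphate transporter (Pavir.7NG027800) was 127-fold higher, at a log2 fold change of 6.99 ± 0.76 (SE). An SPX3-like gene (Pavir.5NG248000), from a family that restrains phosphate starvation signalling, was 32.5-fold higher (5.02 ± 0.36). An AWPM-19-like membrane protein gene (Pavir.2NG274300) was 206-fold lower in the authors' deposited table (−7.69, adjusted p = 1.26e-08).

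In the authors' deposited table for 20 µM P, 70432 loci were tested and 11728 (16.7%) passed an adjusted p of 0.05, with 5255 higher and 6473 lower than in control roots. A change of at least 2-fold was shown by 2561 of the higher and 3823 of the lower loci. The median over all tested loci was −0.01.

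**Figure D1:**
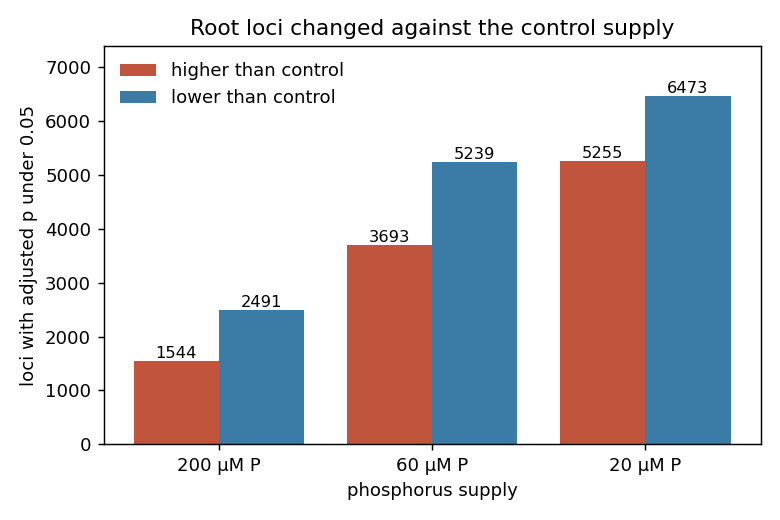
Number of root loci (y axis) with an adjusted p under 0.05 in the authors' deposited tables, against phosphorus supply in µM (x axis). Bars give loci higher (red) and lower (blue) than in control roots; from 200 to 20 µM P the counts went from 1544 to 5255 higher and from 2491 to 6473 lower.

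The 8 largest rises at 20 µM P ranged from 5.98 to 8.03 in the authors' deposited table. They were led by a serine carboxypeptidase-like gene (Pavir.2KG354900, 8.03 ± 1.04) and a cytochrome P450 similar to ent-kaurenoic acid hydroxylase, an enzyme of gibberellin synthesis (Pavir.9KG483200, 7.23 ± 1.00). In the same authors' deposited table, a tetraspanin gene (Pavir.6NG128200) stood at 6.44 ± 0.93 and a major facilitator transporter gene (Pavir.2NG227700) at 6.38 ± 0.95. A gene similar to the thiamine synthesis enzyme THI1 (Pavir.4NG251200) had log2 fold changes of 2.08 ± 0.36, 1.95 ± 0.36 and 6.12 ± 0.36 at 200, 60 and 20 µM P in the authors' deposited tables. The 8 loci all passed the threshold at 60 µM P as well, and 7 of them did at 200 µM P. Besides 2 AWPM-19-like genes, the 8 largest falls held a dehydrin (Pavir.J059500, −6.49 ± 0.72 in the authors' deposited table), an LEA gene (Pavir.6NG226700, −6.38 ± 0.96) and 4 loci described as expressed proteins. Among the latter, Pavir.5KG709200 and Pavir.5KG713600 had nearly equal values in the authors' deposited table (−6.60 ± 1.12 and −6.58 ± 1.12). Whether they are separate changes was not tested. Of the 8 largest falls, 7 passed the threshold at 60 µM P and 2 at 200 µM P.

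By the authors' adjusted p, 57 of 96 tested loci of the 5 lists built around phosphate rose at 20 µM P and 0 fell. The medians of 4 of these lists lay above 0, and the calls adjusted over the list alone, given beside each list, include lower members. Regulators of the SPX and PHR families rose in 8 of 10 tested loci (8 when adjusted over the list alone), with a median log2 fold change of 1.09 (cameraPR adjusted p = 7.02e-16). SPX1-like Pavir.4KG319200 stood at 3.04 ± 0.23 in the authors' deposited table, and a PHR-type MYB gene (Pavir.7KG242700) at 2.29 ± 0.24. Phosphate transport genes rose in 15 of 22 loci (15 higher and 1 lower when adjusted over the list alone), with a median of 2.19 (cameraPR adjusted p = 4.28e-27), or 0.56 over 34 loci with membership by annotation text. A PHT1;7-like transporter (Pavir.3NG105000) was at 4.89 ± 0.36 in the authors' deposited table. Genes of membrane lipid remodelling, which frees phosphate from phospholipids, rose in 17 of 27 loci (18 higher and 1 lower when adjusted over the list alone), with a median of 1.49 (cameraPR adjusted p = 2.81e-36), or 0.68 over 22 loci with membership by annotation text. A pair of NPC4-like phospholipase C genes (Pavir.9NG013100 and Pavir.9KG019500) reached 4.91 ± 0.41 and 4.13 ± 0.41 in the authors' deposited table. These 3 lists were also used to set the sign of the tables, so they are not independent evidence of direction.

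Purple acid phosphatase genes, whose products release phosphate from organic esters, rose in 14 of 28 loci at 20 µM P (15 higher and 1 lower when adjusted over the list alone). Their median was 1.17 (cameraPR adjusted p = 3.80e-15). PAP15-like Pavir.6KG216900 stood at 3.36 ± 0.25 and PAP10-like Pavir.5NG526200 at 2.73 ± 0.18 in the authors' deposited table. In the list of other phosphatases and RNases, 3 of 9 loci rose (3 when adjusted over the list alone). All 3 were similar to small-molecule phosphatases, with PS2-like Pavir.5NG588900 at 4.75 ± 0.23 in the authors' deposited table. This list's median was −0.19, below 0, while its mean (1.09) and its cameraPR test (upward, adjusted p = 1.66e-05) lay above 0, as did the median of 0.21 over 14 loci with membership by annotation text.

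**Figure D2:**
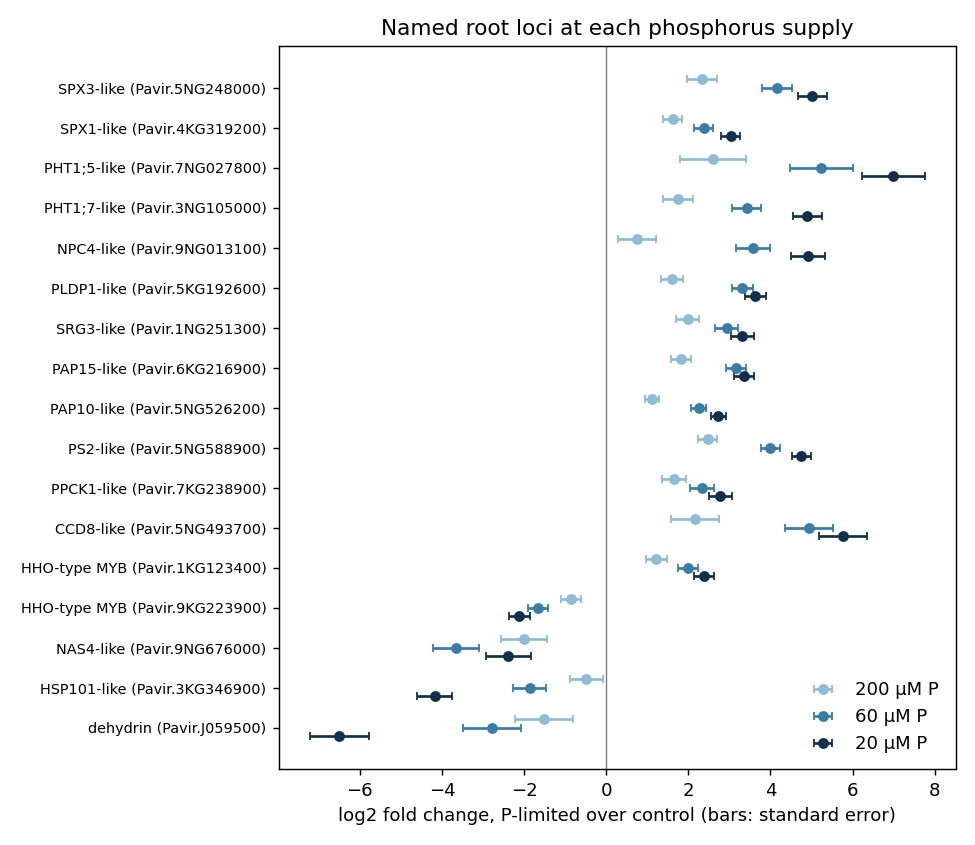
Log2 fold change of 17 named root loci, P-limited over control (x axis), at 200, 60 and 20 µM P (light to dark points), from the authors' deposited tables; bars are the authors' SE. SPX3-like Pavir.5NG248000 stands at 2.34, 4.16 and 5.02, and HSP101-like Pavir.3KG346900 at −0.49, −1.86 and −4.17.

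Strigolactones are root signals made from carotenoids, and their synthesis and perception genes rose in 8 and fell in 3 of 16 loci at 20 µM P (8 and 3 when adjusted over the list alone). The list's median was 1.56 (cameraPR adjusted p = 6.72e-10). CCD8-like Pavir.5NG493700 and Pavir.5KG548600, a pair of carotenoid cleavage dioxygenase genes, stood at 5.76 ± 0.58 and 5.59 ± 0.52 in the authors' deposited table, and D27-like Pavir.8NG268500 at 4.06 ± 0.50. Genes of the glycolytic bypass, whose enzymes avoid phosphate-dependent steps of glycolysis, rose in 9 of 21 loci (9 when adjusted over the list alone), with a median of 0.45 (cameraPR adjusted p = 1.36e-06), or 0.28 over 32 loci with membership by annotation text. Among them, PPCK1-like Pavir.7KG238900 was at 2.78 ± 0.29 and PEPC3-like Pavir.1KG176500 at 2.56 ± 0.41 in the authors' deposited table. The PEPC3-like locus did not pass the threshold at 200 or 60 µM P, and it was also higher in the undescribed groups (values below). Root hair genes rose in 2 of 12 loci at 20 µM P (6 when adjusted over the list alone), with a median of 0.97 (cameraPR adjusted p = 0.00619). Membership by annotation text gave a median of 0.13 over 18 loci, inside the range of random lists, with 1 higher and 1 lower. The 2 risen loci of the list by Arabidopsis hit were similar to expansin A7 (Pavir.4KG008500, 1.39 ± 0.43 in the authors' deposited table) and to the bHLH factor RSL1 (Pavir.5KG143400, 0.99 ± 0.33). Among expansin genes, whose products loosen cell walls, 13 rose and 5 fell of 89 (16 and 5 when adjusted over the list alone). Their median was 0.19 (cameraPR adjusted p = 0.200), just above the range of random lists (−0.18 to 0.17). Of 11 organic acid channel and carrier loci, 1 fell (0 when adjusted over the list alone; median 0.04, cameraPR adjusted p = 0.992), and the median was −0.15 with membership by annotation text.

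Genes for other nutrients were mixed at 20 µM P. By Arabidopsis hit, the nitrogen and iron medians lay below the range of random lists, although neither list passed cameraPR. In the nitrogen list, 2 loci rose and 9 fell of 31 (5 and 9 when adjusted over the list alone), with a median of −0.33 (cameraPR adjusted p = 0.177), or −0.09 over 49 loci with membership by annotation text. NRT2.1-like Pavir.J648900, a nitrate transporter gene, stood at −2.41 ± 0.65 in the authors' deposited table, while an AMT2-like ammonium transporter (Pavir.5KG657600) stood at 2.07 ± 0.72. Of 6 loci of the NIGT1/HHO family, MYB-type factors known to link nitrate and phosphate responses, 1 rose (Pavir.1KG123400, 2.38 ± 0.25 in the authors' deposited table) and 2 fell (1 and 2 when adjusted over the list alone). One of the latter was Pavir.9KG223900, at −2.11 ± 0.25 in the authors' deposited table; the list's median was −0.52 (cameraPR adjusted p = 0.540). Iron homeostasis genes rose in 3 and fell in 5 of 18 loci (3 and 6 when adjusted over the list alone), with a median of −0.47 (cameraPR adjusted p = 0.200), or −0.31 over 11 loci with membership by annotation text. The falls included NAS4-like nicotianamine synthase Pavir.9NG676000, at −2.38 ± 0.56 in the authors' deposited table. In the sulfate list 1 locus rose and 1 fell of 11 (1 and 1 when adjusted over the list alone). Its median was −0.22 against a mean of 0.02 and an upward cameraPR direction (adjusted p = 0.704), and with membership by annotation text the median was 0.45.

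The ethylene and auxin lists held 4 called loci each at 20 µM P. Ethylene synthesis genes rose in 1 and fell in 3 of 20 loci (1 and 6 when adjusted over the list alone), with a median of −0.85 (cameraPR adjusted p = 0.127), or −0.33 over 41 loci with membership by annotation text. The median of −0.85 lay below the range of random lists (−0.39 to 0.37), so these tests differ. The 1 that rose was an ACC oxidase gene (Pavir.9NG329100, 3.55 ± 0.58 in the authors' deposited table). Auxin response genes fell in 4 of 18 loci (4 when adjusted over the list alone), among them the Aux/IAA gene Pavir.2KG089500 at −1.84 ± 0.24 in the authors' deposited table. This list's median was 0.00, its mean was −0.24 and its cameraPR direction was downward (adjusted p = 0.0804). Phenylpropanoid and lignin genes rose in 3 and fell in 1 of 84 loci (3 and 1 when adjusted over the list alone; median −0.06, cameraPR adjusted p = 0.567). Flavonoid genes fell in 2 of 63 (2 when adjusted over the list alone; median 0.00, cameraPR adjusted p = 0.567). Class III peroxidase genes rose in 16 and fell in 12 of 202 (16 and 12 when adjusted over the list alone; median 0.03, cameraPR adjusted p = 0.397).

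Heat shock genes, fixed as signs of handling stress, rose in 2 and fell in 18 of 37 loci at 20 µM P (2 and 22 when adjusted over the list alone), with a median of −1.36 (cameraPR adjusted p = 6.72e-10). HSP101-like Pavir.3KG346900 stood at −4.17 ± 0.43 in the authors' deposited table. With membership by annotation text, which takes in all 319 heat shock loci tested, 32 rose, 51 fell and the median was −0.05. Ribosomal protein genes, organellar ones included, rose in 7 and fell in 83 of 572 loci (7 and 81 when adjusted over the list alone), with a median of −0.28 (cameraPR adjusted p = 1.99e-05). Against that direction, an S15A-like ribosomal protein locus (Pavir.5NG580400) stood at 4.59 ± 0.32 in the authors' deposited table. Of the 23 photosynthesis marker loci, fixed as markers of shoot tissue, 1 fell (0 when adjusted over the list alone), with a median of −0.36 (cameraPR adjusted p = 0.241). With membership by annotation text, 1 photosynthesis locus rose and 23 fell of 82, with a median of −0.69. The list of chitinases and symbiosis-annotated genes, fixed as a sign of other organisms, had 3 higher and 9 lower of 62 loci (3 and 11 when adjusted over the list alone; median −0.21, cameraPR adjusted p = 0.386). Histone and mitotic cyclin genes, markers of dividing tissue, had 0 members passing among 15 loci (0 when adjusted over the list alone; median −0.33, cameraPR adjusted p = 0.317). Housekeeping genes rose in 3 and fell in 4 of 52 loci (3 and 4 when adjusted over the list alone; median −0.10, cameraPR adjusted p = 0.567).

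**Figure D3:**
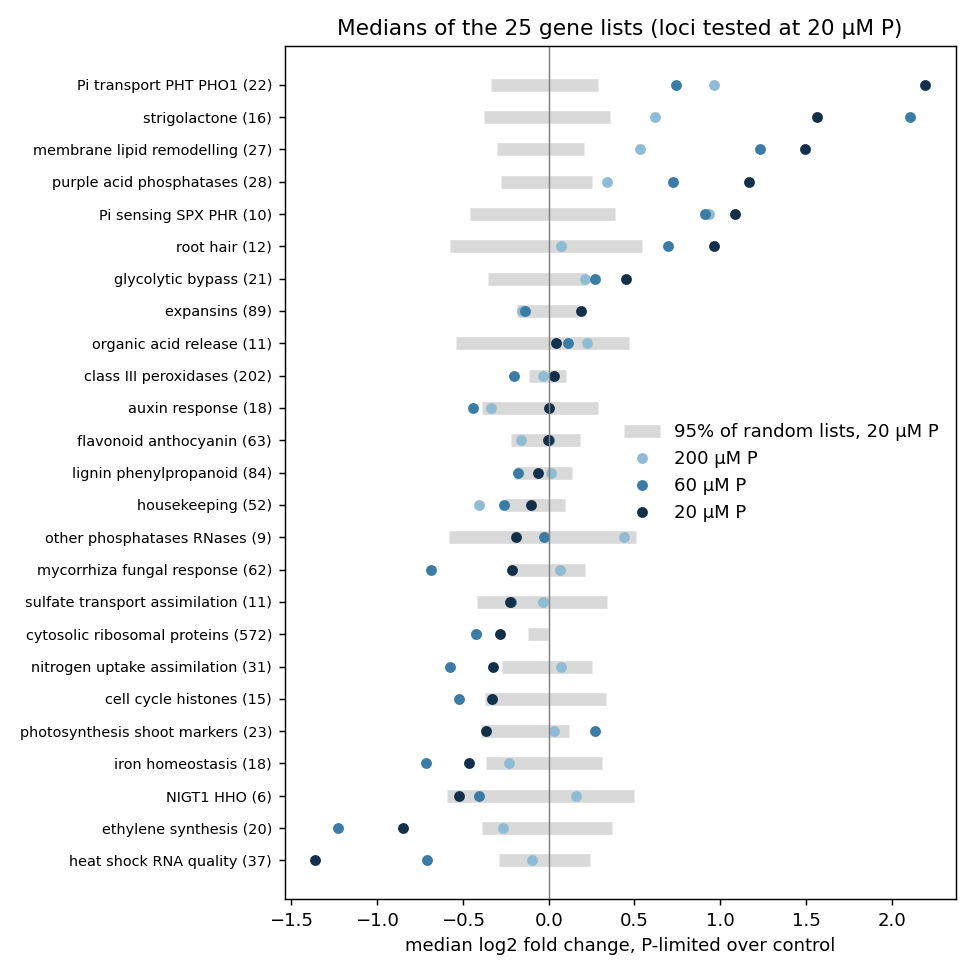
Median log2 fold change, P-limited over control (x axis), of the 25 gene lists (y axis, with the number of loci tested at 20 µM P) at 200, 60 and 20 µM P (light to dark points). Grey bars span the central 95% of medians of 10000 matched random lists at 20 µM P; the medians of 13 lists lie outside.

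At 60 µM P, the medians of 4 of the 5 phosphate lists and of the strigolactone list were again above 0. By the authors' deposited table, SPX3-like Pavir.5NG248000 stood at 4.16 ± 0.36, PHT1;5-like Pavir.7NG027800 at 5.24 ± 0.77 and PS2-like Pavir.5NG588900 at 4.00 ± 0.23. A class 3 lipase gene (Pavir.8KG375100) was 56.6-fold higher in the authors' deposited table (5.82 ± 0.38). Ethylene synthesis, auxin response, iron, nitrogen and ribosomal protein genes were lower as lists, and so were the lists fixed as markers of other organisms, dividing tissue and handling, and the housekeeping list. Not all of this was limited to P supply. The iron, ribosomal protein, other-organism and dividing-tissue lists also had medians below the range of random lists in N02R, N06R and N2R, which share the control. In the authors' deposited table for 60 µM P, 8932 of 68514 tested loci (13.0%) passed the threshold, 3693 higher and 5239 lower.

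The serine carboxypeptidase-like gene Pavir.2KG354900 also had the highest rise at 60 µM P (7.44 ± 1.04 in the authors' deposited table). The 5 largest falls included an aldo/keto reductase gene (Pavir.9NG846500), which stood at −3.45 ± 0.63, −5.47 ± 0.65 and −3.10 ± 0.63 at 200, 60 and 20 µM P in the authors' deposited tables. SPX and PHR loci rose in 6 of 10 at 60 µM P (8 when adjusted over the list alone; median 0.91). Phosphate transport loci rose in 13 and fell in 1 of 22 (14 and 1 when adjusted over the list alone; median 0.74). Lipid remodelling loci rose in 15 of 26 (16 when adjusted over the list alone; median 1.23), with PLDP1-like Pavir.5KG192600, a phospholipase D gene, at 3.32 ± 0.26 in the authors' deposited table. Purple acid phosphatase loci rose in 11 of 28 (12 when adjusted over the list alone; median 0.72). In the list of other phosphatases and RNases 3 rose and 1 fell of 9 (3 and 2 when adjusted over the list alone), with a median of −0.03 against a mean of 0.73 and an upward cameraPR direction (adjusted p = 0.000671). Strigolactone loci rose in 8 and fell in 3 of 15 (9 and 4 when adjusted over the list alone; median 2.11). Glycolytic bypass loci rose in 6 of 19 (7 higher and 1 lower when adjusted over the list alone), with a median of 0.27 (cameraPR adjusted p = 0.00392). Of 12 root hair loci 1 rose (0 when adjusted over the list alone), with a median of 0.70 (cameraPR adjusted p = 0.0379). Ethylene synthesis loci fell in 8 of 20 (1 higher and 12 lower when adjusted over the list alone), with a median of −1.23 (cameraPR adjusted p = 2.00e-05). Auxin response loci fell in 7 of 18 (7 when adjusted over the list alone), with a median of −0.44 (cameraPR adjusted p = 2.17e-05). Nitrogen loci fell in 9 of 30 (1 higher and 9 lower when adjusted over the list alone), with a median of −0.57 (cameraPR adjusted p = 0.00136). Iron loci rose in 2 and fell in 6 of 18 (2 and 9 when adjusted over the list alone), with a median of −0.71 (cameraPR adjusted p = 0.00174). Heat shock loci rose in 1 and fell in 12 of 36 (3 and 16 when adjusted over the list alone), with a median of −0.71 (cameraPR adjusted p = 0.00105). Ribosomal protein loci rose in 4 and fell in 161 of 569 (5 and 210 when adjusted over the list alone), with a median of −0.43 (cameraPR adjusted p = 2.70e-14). Chitinases and symbiosis-annotated genes rose in 2 and fell in 11 of 57 (2 and 13 when adjusted over the list alone), with a median of −0.68 (cameraPR adjusted p = 0.00172). Of 15 histone and mitotic cyclin loci 1 fell (0 when adjusted over the list alone), with a median of −0.52 (cameraPR adjusted p = 0.00789). The photosynthesis markers had 1 higher and 0 lower of 23 at this supply (0 when adjusted over the list alone), and the housekeeping list had 2 higher and 11 lower of 52 (2 and 16 when adjusted over the list alone), with a median of −0.26 (cameraPR adjusted p = 0.00127).

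At 200 µM P, the medians of the 5 phosphate lists lay above 0, and ribosomal protein genes were lower as a list. By the authors' deposited table, PS2-like Pavir.5NG588900 stood at 2.48 ± 0.23, SPX3-like Pavir.5NG248000 at 2.34 ± 0.36 and PHT1;5-like Pavir.7NG027800 at 2.60 ± 0.81. An SRG3-like glycerophosphodiester phosphodiesterase gene (Pavir.1NG251300) was 3.97-fold higher in the authors' deposited table (1.99 ± 0.28). In the authors' deposited table for 200 µM P, 4035 of 62752 tested loci (6.43%) passed the threshold, 1544 higher and 2491 lower.

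SPX and PHR loci rose in 5 of 10 at 200 µM P (7 when adjusted over the list alone; median 0.93). Phosphate transport loci rose in 8 of 18 (9 when adjusted over the list alone; median 0.96), and lipid remodelling loci in 9 of 25 (13 higher and 1 lower when adjusted over the list alone; median 0.53). Purple acid phosphatase loci rose in 4 of 28 (4 when adjusted over the list alone; median 0.34). In the list of other phosphatases and RNases 2 rose and 1 fell of 7 (3 and 1 when adjusted over the list alone; median 0.44). Strigolactone loci rose in 4 of 15 (5 when adjusted over the list alone), with a median of 0.62 (cameraPR adjusted p = 0.00102). Glycolytic bypass loci rose in 5 of 18 (6 higher and 1 lower when adjusted over the list alone), with a median of 0.21 (cameraPR adjusted p = 0.000658). Auxin response loci fell in 4 of 18 (4 when adjusted over the list alone), with a median of −0.34 (cameraPR adjusted p = 0.00143). Ribosomal protein loci rose in 4 and fell in 136 of 553 (7 and 217 when adjusted over the list alone), with a median of −0.42 (cameraPR adjusted p = 9.77e-20). Housekeeping loci rose in 1 and fell in 11 of 52 (1 and 22 when adjusted over the list alone), with a median of −0.41 (cameraPR adjusted p = 5.04e-09). Of 15 histone and mitotic cyclin loci 1 fell at this supply (1 when adjusted over the list alone), with a median of −0.33 (cameraPR adjusted p = 0.0364). Heat shock loci rose in 1 and fell in 4 of 32 (1 and 4 when adjusted over the list alone; median −0.10), and 0 of 23 photosynthesis markers passed either adjustment. The ethylene list's median was −0.27 there, while its cameraPR direction was upward (adjusted p = 0.940). The largest rise was a cysteine-rich receptor-like kinase gene (Pavir.4NG094500), at 6.25 ± 1.30 in the authors' deposited table, against 1.22 ± 1.33 and 1.09 ± 1.33 at 60 and 20 µM P. Of the 5 largest falls at 200 µM P, 0 passed the threshold at 60 µM P and 1 did at 20 µM P. A sterol C4-methyl oxidase gene (Pavir.3NG192200) among them stood at −4.51 ± 1.08, −0.25 ± 1.07 and −0.85 ± 1.07 at 200, 60 and 20 µM P in the authors' deposited tables.

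Across the 3 supplies, most phosphate genes called at 60 µM P moved in order of P supply. Of 49 loci of the 5 phosphate lists called at 60 µM P and tested at every supply, 48 had the same sign at all 3, and in 42 the size of the change grew from 200 to 60 to 20 µM P. That is 85.7%, against 15.8% for the same lists when an equal response at every supply was simulated, with noise drawn separately for each locus. All 11 such purple acid phosphatase loci followed that order, as did 14 of 15 lipid remodelling loci, 10 of 13 phosphate transport loci, 4 of 6 SPX and PHR loci and 3 of 4 loci of other phosphatases and RNases. The medians over all tested members of a list were not always in this order: at 200, 60 and 20 µM P they were 0.96, 0.74 and 2.19 for phosphate transport and 0.93, 0.91 and 1.09 for SPX and PHR regulators. The phosphate transport medians rest on 18, 22 and 22 tested loci, so they do not compare the same loci. NPC4-like Pavir.9NG013100 had log2 fold changes of 0.75 ± 0.45 (adjusted p = 0.372), 3.57 ± 0.42 and 4.91 ± 0.41 in the authors' deposited tables at 200, 60 and 20 µM P.

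Over all 16175 loci called at any supply, 81.6% had the same sign at the 3 supplies. A simulated equal response, with loci called on its own values, gave 99.0%. Simulated unchanged groups sharing the control gave 49.3% over the loci called in the data. Those loci were not selected by their simulated values, so 49.3% is no like floor for the 81.6%. With the same sign and in that order of size, 30.2% of the 16175 loci were graded, while 6.85% had the reverse order. With an equal response at every supply simulated and the loci called in the same way, 16.3% were graded, at most 16.9% in any of 100 sets, and 16.8% had the reverse order. The noise was drawn separately for each locus, so this narrow range leaves out shifts that many loci share. A response that levels off at 60 µM P was not simulated. Among the 8800 loci called at 60 µM P, a selection added after seeing the data that uses neither end of the series, 27.9% were graded (14.9% for an equal response). Calls shared by all 3 supplies numbered 612 higher and 926 lower, against 7.34 and 20.7 for independent lists, a reference that leaves the shared control out of account. Simulated unchanged groups had 0 shared calls, as groups without change give almost no calls at all, so they set no level for the overlap. Opposite calls were made for 17 loci between 200 and 60 µM P, 7 between 60 and 20 µM P, and 17 between 200 and 20 µM P. Across the 62752 loci tested at every supply, which are not independent replicates, Pearson's r of the log2 fold changes was 0.56 between 200 and 60 µM P, 0.73 between 60 and 20 µM P and 0.55 between 200 and 20 µM P, against 0.474, 0.478 and 0.479 in simulated unchanged groups sharing the control. The covariances were 0.313, 0.525 and 0.342, against 0.121 in each simulation of a shared control. The simulated r and covariances rest on the assumed part of the control in the SE, which is not given. A noisier control would raise them, so the excess over them is uncertain. All 3 comparisons use the same control libraries, which could not be divided. Between 20 µM P and the undescribed groups N02R, N06R and N2R, r was 0.60, 0.54 and 0.52, against 0.479, 0.474 and 0.477 in such simulations. Loci called both at 20 µM P and in N02R numbered 2666 higher, 3541 lower and 279 opposite. Shared calls and correlations were thus not limited to the 3 P supplies. Tested directly, 613 loci differed between 60 and 200 µM P, 1298 between 20 and 200 µM P, and 153 between 20 and 60 µM P, of which 43 were higher and 110 lower at 20 µM P.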

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

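All tests weighed in this part were chosen after the pattern had been seen, except that those for the LEA and dehydrin genes were written before their results were computed.

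Tables of 3 further groups, which the labels do not describe, held many calls against the same control roots. In the authors' deposited tables, 16631 loci passed the threshold for N02R, 13246 for N06R and 8220 for N2R. What these groups received is not stated, so no cause of their calls was tested.

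In these tables the phosphate lists held loci that differed from 20 µM P. PS2-like Pavir.5NG588900, which was 26.9-fold higher at 20 µM P, was 2.42-fold lower in N02R, 2.36-fold lower in N06R and 2.57-fold lower in N2R by the authors' deposited tables. Phosphate transport loci were higher at 20 µM P than in N02R in 17 of 22, than in N06R in 16 of 22 and than in N2R in 14 of 18, in a test of the difference itself, and lower in 3, 3 and 2. Purple acid phosphatase loci were higher at 20 µM P in 14, 13 and 14 of 28. Against control, these phosphatase loci rose in 1, 1 and 0 and fell in 7, 10 and 10, with medians of −0.46, −0.68 and −0.54. Phosphate transport loci rose against control in 1, 4 and 3 and fell in 6, 5 and 3 of 23, 22 and 18. The differences from 20 µM P thus include falls in these groups. SPX and PHR loci were higher at 20 µM P in 4, 4 and 6 of 10 and lower in 2, 1 and 0, and their medians in N02R, N06R and N2R were 0.50, 0.44 and −0.10. Lipid remodelling loci were higher at 20 µM P in 16 of 27, 17 of 27 and 16 of 25 and lower in 3, 3 and 0; against control they rose in 7 and fell in 2 of 27 in N02R and in N06R, and rose in 3 of 25 in N2R. Genes of nitrogen uptake and assimilation rose in 11 and fell in 6 of 32 loci in N02R, rose in 14 and fell in 4 of 31 in N06R, and rose in 10 of 29 in N2R. An AMT2-like ammonium transporter (Pavir.5KG657600) was 51.2-fold, 47.2-fold and 12.8-fold higher there in the authors' deposited tables. The 23 photosynthesis markers fell in 16, 13 and 14 loci. The iron list, with a median of −0.71 at 60 µM P, had medians of −1.56, −1.23 and −1.43 in N02R, N06R and N2R. Chitinases and symbiosis-annotated genes, at −0.68 at 60 µM P, had medians of −1.10, −1.13 and −0.71 there. A high level of either list in the shared control roots was not tested. CCD8-like Pavir.5NG493700 was higher in all 3 as well, by 47.6-fold, 44.2-fold and 14.2-fold in the authors' deposited tables, against 54.3-fold at 20 µM P. The glycolytic bypass list rose in 8, 7 and 9 loci and fell in 1, 0 and 1 there, with medians of 0.11, 0.03 and 0.33. PEPC3-like Pavir.1KG176500 stood at 3.00, 3.25 and 2.45 (log2) in the authors' deposited tables, and PPCK1-like Pavir.7KG238900 at −1.05, −0.08 and 0.11. The 2 highest rises named at 20 µM P were higher there too: in N02R, N06R and N2R the carboxypeptidase-like Pavir.2KG354900 stood at 5.44, 5.11 and 4.00 and the P450 Pavir.9KG483200 at 7.98, 8.37 and 6.06 (log2) in the authors' deposited tables, against 8.03 and 7.23 at 20 µM P. The next 2 by size were not: PHT1;5-like Pavir.7NG027800 stood at −0.33, −0.45 and −1.53 and Pavir.2NG320200 at −0.30, −0.44 and −0.68. Among the largest falls, AWPM-19-like Pavir.2NG274300 stood at −3.63, −3.07 and −0.60 there and the dehydrin Pavir.J059500 at −5.25, −3.44 and −0.85.

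Ribosomal protein genes fell at all 3 P supplies, by medians of −0.42, −0.43 and −0.28 at 200, 60 and 20 µM P, and the housekeeping list had medians of −0.41, −0.26 and −0.10 beside them. A fall that grows with P limitation was not seen in these values. The per-gene difference between 20 and 200 µM P had a median of 0.14 (95% bootstrap interval over genes 0.11 to 0.17), toward a smaller fall. That interval takes genes as units and leaves out the spread between libraries, so it does not decide the question. A high level in the shared control roots may contribute: the list was also lower in N02R, N06R and N2R, with medians of −0.70, −0.57 and −0.38. Histone and mitotic cyclin genes had medians of −1.24, −0.78 and −0.57 there, and −0.33, −0.52 and −0.33 at 200, 60 and 20 µM P. What the undescribed groups received is not stated, so they are no neutral reference and cannot single out the control. A lowering of these genes by P limitation at all 3 supplies was not tested apart from the control level, and it stays open as the biological alternative.

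Dehydrin and LEA genes, a list added after the data had been seen, fell in 39 and rose in 5 of 161 loci at 20 µM P (median −0.32), fell in 27 and rose in 2 of 154 at 60 µM P (−0.49), and fell in 10 of 139 at 200 µM P (−0.20). Per gene, the median difference between 20 and 200 µM P was −0.13 (95% bootstrap interval over genes −0.25 to −0.03), which leaves out the spread between libraries. The list's means were −0.46, −0.71 and −1.01 at 200, 60 and 20 µM P, below the medians, so large falls of some genes weigh in. A dehydrin and an LEA gene were among the largest falls at 20 µM P, so a list added after that favours a lower value there. The list was also lower in N02R, N06R and N2R, with medians of −0.76, −0.55 and −0.40, but the treatment of these groups is not stated. Heat shock genes, fixed as a sign of handling, had medians of −0.10, −0.71 and −1.36 at 200, 60 and 20 µM P, and −0.90, −0.13 and −0.51 in N02R, N06R and N2R. Both a high level in the control roots and a fall that grows as P falls stay possible, and neither these nor a difference in handling are separated by these tables.

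Loci without a reference gene made up 87 of the 100 loci of highest baseMean, and those 100 held 54.6% of the summed baseMean. Of the 87, 42 fell and 5 rose at 20 µM P, with a median of −0.72. Their medians were −0.49 and −0.35 at 200 and 60 µM P, and −0.91, −0.63 and −0.53 in N02R, N06R and N2R. They were thus lower in every comparison with the shared control, and a high level in that control was not tested. An effect of these loci on the scaling of all other genes stays open: the median of tested loci with a reference gene was 0.00545 at 20 µM P, but scaling between libraries itself centres this median, so a value near 0 does not decide. Reads of 1 repeated sequence counted at several loci stay a possible explanation as well: within runs of neighbouring locus numbers the SD of the log2 fold changes was 0.499 against a median SE of 0.354, which lies between the bounds set for and against it. No biological explanation was tested for these loci.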

How the results depend on the processing

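The restriction to loci with a reference gene and the graded share over loci called at 60 µM P were chosen after seeing the data, and the other alternatives were planned. Counts moved by over 1.5 times only where the criterion itself was stricter or fewer loci were counted. At 200, 60 and 20 µM P, called loci numbered 1784, 5143 and 7047 at an adjusted p under 0.01, 1809, 4610 and 6384 with a change of at least 2-fold, 405, 1378 and 2076 after Bonferroni adjustment, and 2510, 5731 and 7431 among loci with a reference gene. Calls shared by all 3 supplies numbered 670 at an adjusted p under 0.01, against 1538. Filters at a baseMean of 1 or 5 with recomputed adjustment gave 3557 and 3992, 8409 and 8985, and 11200 and 11820 calls. Centring on the median or a trimmed mean moves every locus of a comparison alike and by far less than the change of any named gene, so it tests nothing for them. Among the 120 results for named genes, the call was lost in 15 at an adjusted p under 0.01, in 46 after Bonferroni adjustment, in 1 with a baseMean of 1 or more and in 2 with 5 or more.

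The graded share was 35.4% at an adjusted p under 0.01 and 27.9% for loci called at 60 µM P. A baseMean filter of 1 removed no tested locus, so for these results and the lists it tests nothing. At 20 µM P the medians of 13 of 25 lists lay outside the central 95% of random lists, 12 of the 23 lists that could be built by annotation text did with that membership, and 10 lists passed cameraPR. The ethylene, nitrogen, iron and expansin medians lay outside that range without passing cameraPR. The list of other phosphatases passed cameraPR with its median inside the range. With membership by annotation text the sulfate list turned from −0.22 to 0.45 (7 of 16 loci rose), and the cause was not tested. Inside the random range, the medians of the other phosphatases (−0.19 to 0.21), organic acid (0.04 to −0.15) and auxin lists (0.00 to −0.01) also changed sign; the nitrogen, iron, root hair and heat shock lists, at −0.09, −0.31, 0.13 and −0.05, returned inside the random range, and the photosynthesis and histone lists, at −0.69 and −0.27, left it.

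No paired analysis was possible because the tables give no values per library. For the same reason the replicate block, leaving out each replicate, other splits of the libraries, other pseudocounts, count-based tests, an estimated correlation and a division of the control libraries were not run, and no shoot comparison was run. Depth is unknown. If the fold changes were shrunk by a prior, which was inferred only from the ceiling of the SE, those of weakly expressed loci are understated.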

Other observations

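The tests of Gene Ontology terms in this part were chosen after the data had been seen. They take loci as independent, so copies of a gene in the K and N subgenomes count separately. They also do not adjust for expression level or transcript length, so no cause can be read from the enriched terms. Among loci higher at 20 µM P, Ran GTPase binding, which marks nuclear import receptors, held 12 higher of 18 tested loci against 1.76 expected (adjusted p = 2.87e-06), and microtubule motor activity held 28 of 93 against 9.08 (adjusted p = 4.37e-06). Intracellular protein transport held 32 of 139 (adjusted p = 0.000172) and proton transport 9 of 15 (adjusted p = 0.000143), and the broad term transport held 70 of 397 (adjusted p = 6.99e-05). ATPase activity coupled to transmembrane movement held 24 of 93 (adjusted p = 0.000282) and transporter activity 44 of 253 (adjusted p = 0.00418). Microtubule motor loci were also enriched among those higher at 60 µM P, with 21 of 93 (adjusted p = 2.30e-05).

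Among loci lower at 20 µM P, photosynthesis held 22 of 61 against 5.38 expected (adjusted p = 1.56e-06) and protein serine/threonine phosphatase activity 27 of 104 (adjusted p = 3.19e-05). Threonine-type endopeptidase activity, the term of the proteasome core, held 14 lower of 41 loci at 20 µM P (adjusted p = 0.000273), 22 of 41 at 60 µM P (adjusted p = 2.35e-11) and 20 of 40 at 200 µM P (adjusted p = 5.72e-15). Ribosome constituents held 65 lower of 447, 127 of 445 and 107 of 430 in the same order.

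The S15A-like ribosomal protein locus Pavir.5NG580400 was 24.1-fold higher at 20 µM P, where the ribosomal list's median was −0.28, by the authors' deposited table. It was 3.74-fold, 7.19-fold and 6.65-fold lower in N02R, N06R and N2R by the authors' deposited tables, where the list's medians were also below 0 (−0.70, −0.57 and −0.38). A GAPDH-like locus (Pavir.5NG493500) of the housekeeping list stood at 3.06 ± 0.71 at 20 µM P in the authors' deposited table, while 4 loci of that list fell.

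The subgenomes had like shares of called loci. At 20 µM P, 7.94% of 21812 tested K loci rose and 8.83% fell, and 8.27% of 20523 N loci rose and 8.59% fell, with no test made of these shares. A run of 9 neighbouring locus numbers among the loci of highest baseMean, without reference genes, held 5.08% of the summed baseMean, and 8 of the 9 fell at 20 µM P with a median of −2.94.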
